A study of Mus musculus with 8 samples.

How the data were processed

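Per the labels, the samples were macrophages grown for 7 days with M-CSF from the bone marrow of C57BL/6 mice, in 4 groups of 2 samples, and both ATRA, at 1 µM, and OMsup acted for 24 h in a medium without serum. Per the labels, RNA was isolated with RNeasy micro columns and DNase, amplified to biotin-labelled cRNA with the Ambion MessageAmp chemistry and hybridized to an Illumina mouse whole-genome bead array in 1 colour. The labels do not say whether replicates came from separate cultures or animals, whether untreated cells received a medium change, or which chip held which sample. The p-values therefore measure only the spread between these samples, which may be technical. The software behind the deposited tables is not given in the sources used here.

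The deposited table of non-normalized values gave an intensity and a detection p-value per probe and array. The authors' intensity is on a linear scale without background subtraction, as its values show: array medians ran from 92.59 to 98.21, and undetected probes had medians of 89.82 to 94.4. Per the file headers the detection p-value belongs to each array. A deposited normalized matrix held quantile-normalized linear intensity, with array medians of 95.07 to 95.08, and each of its columns was checked to correlate best with its own array. It was used only as an alternative. Empty lines of the probe table, 1348 in all, were left out.

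The main analysis used limma 3.58.1 in R 4.3.3. Background and quantile normalization were done with neqc, with negative controls inferred from the detection p-values and an offset of 16, and values were put on the log2 scale. Probes with a detection p under 0.05 on at least 2 arrays were kept, 18503 of 45281. A symbol was represented by its brightest detected probe, which left 10068 named genes and 2725 probes without a symbol, 12793 in all. Gene symbols came from a probe table checked by gene number: 34885 probes had 1 symbol, 18 had several and 10378 had none. Files without a genome build were used, so no coordinates are given.

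Group means were fitted to the 8 arrays together with lmFit and tested with eBayes with a trend, and p-values were adjusted by Benjamini and Hochberg's method within each comparison, with 0.05 as the limit. The comparisons were each treated group against untreated, ATRA+OMsup against ATRA and against OMsup, and the interaction, which is the ATRA effect with OMsup minus the ATRA effect without it. The prior added 6.62 degrees of freedom to the 4 of the residuals. The median SE was 0.171, or 0.242 for the interaction. At an unadjusted p under 0.05 the 6 comparisons had 1757, 2638, 3472, 2748, 1729 and 670 genes or probes.

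Gene lists were written before the data were examined, from general knowledge of the field, which may include the publication of this study. They covered 20 groups: retinoic acid receptor targets, large peritoneal macrophage genes, MHC class II, type I interferon response, NF-kB driven genes, alternative activation, cholesterol biosynthesis, LXR targets and PPAR targets. The others were cell cycle, hypoxia and glycolysis, TGF-beta response, unfolded protein and amino acid stress, NRF2 targets, glucocorticoid response, IL-6 and STAT3 response, complement and apoptotic cell uptake, osteoclast genes, macrophage identity and immediate early genes. Of 353 listed genes, 324 had a probe and 269 were tested. Lists were tested against all other genes with camera at a preset correlation of 0.01, with p adjusted over the 20 lists of a comparison. Each list call is given beside camera with the correlation estimated from the residuals, and fry was run as well. Of 120 list tests 62 were calls, 39 up and 23 down, and 15 held with an estimated correlation. With fry, which tests a list by itself and not against the other genes, 7 of the 62 calls ended. "Adjusted over the list alone" means that the limma p-values were adjusted over the members of that list only. Marker lists of mesothelial, adipocyte, fibroblast, B, T and NK, granulocyte, dendritic and mast cells were counted; a megakaryocyte and platelet list was written after the leading genes were seen and before it was tested.

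Genes are named by a rule set in advance: 10 key genes (Gata6, Rarb, Tgfb2, Ltbp1, Arg1, Cyp26b1, Tgm2, Aldh1a2, Alox15, Apoc2), the largest changes and list members. The largest changes were the 8 largest rises and falls against untreated cells and the 5 largest in the other comparisons among genes that passed with both arrays beyond both of the other group. Of each list up to 4 of the largest called members were taken, or the 2 largest where none passed. Beyond the key genes and those largest changes, values are given mainly for list members whose call held under every alternative run for single genes, which leaves out probes taken singly and the 2-fold limit, and the rest are counted. Interaction genes needed only an adjusted p under 0.05. Probes without a symbol, or with several, are not named. Of the largest falls with ATRA, 1 gene is not reported here. Ltbp1 had 1 of 7 probes above background. Of 204 values from other probes of named genes, 10 had the opposite sign to a called change, in Angptl4, Dhrs3, Egr3, Kif23, Lss, Nr1h3 and Stab1. Some others kept the sign but were far smaller. With OMsup these included Egln3 (0.156 against 3.647 for the probe used), Gsta3 (0.309 against 2.697) and Pfkl (0.615 against 2.42).

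Where a gene was not above background on either array of 1 group, its fold is given as a bound against the lowest detected level of the arrays, for its brightest detected probe. A second probe of Cxcl2 was above background on 1 OMsup array, so that gene is given no bound. With members set to their bound, list medians moved by at most 0.38 and 1 of 100 list and comparison pairs changed sign.

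The tests were tested on simulated data with the size and spread of these arrays, 10 simulations with 200 planted genes. For ATRA against untreated 16% of planted changes of 0.5 were recovered, 93% of 1 and 100% of 2, and 4.63% of calls were false. For the interaction 3.2%, 57% and 99.8% were recovered, with 6.14% false, so a change near 1 was often missed there. In simulations camera found 10 of 10 lists shifted by 0.5 and called 0 of 190 unchanged ones. Genes were drawn independently of each other there. The result therefore does not show how often camera at a preset correlation errs on lists whose genes move together. Effects that share the untreated arrays were set beside 100 simulations of unchanged groups with the same controls.

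The alternatives were no background correction, normexp without controls at an offset of 50, neqc at an offset of 50, scaling to a common median, cyclic loess, the deposited normalized values, no filter, detection p under 0.01 and detection on all 8 arrays. Others were the mean of a gene's probes, all probes singly, eBayes without trend and with robust fitting, only the 2 groups compared, the replicate number as a block, array weights, each array left out, and changes of at least 2-fold. For correlations, called genes only were tried too. When 1 array was left out, the remaining array of its group was assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.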

Results

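Gene expression was measured in mouse bone marrow derived macrophages, which are macrophages grown from bone marrow in culture, here from C57BL/6 mice over 7 days with the growth factor M-CSF. The cells were left untreated or were stimulated for 24 h with 1 µM all-trans retinoic acid (ATRA), with culture supernatant of omentum (OMsup), or with both (ATRA+OMsup). The labels do not say whether untreated cells also received the medium without serum. Differences from untreated cells may therefore include an effect of the medium. ATRA is the vitamin A metabolite that activates nuclear retinoic acid receptors. The omentum is a fatty tissue of the abdominal cavity. Each of the 4 groups held 2 arrays, 8 in all, of a whole-genome Illumina bead array with 45281 probes. Between 16116 and 16784 probes per array were above background, and 12793 genes or unnamed probes were tested. The replicate arrays of a group correlated across probes at 0.9905 to 0.9939. In a principal component analysis the first component, with 48.6% of the variance, separated the arrays with OMsup from those without, and the second, with 25.1%, separated the arrays with ATRA from those without. The comparisons asked which genes each agent changed, which changed with the combination, and where the effect of one depended on the other. All changes are log2 differences of normalized intensity with the standard error (SE) of the fit, and n = 2 arrays in each group throughout.

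**Figure D1:**
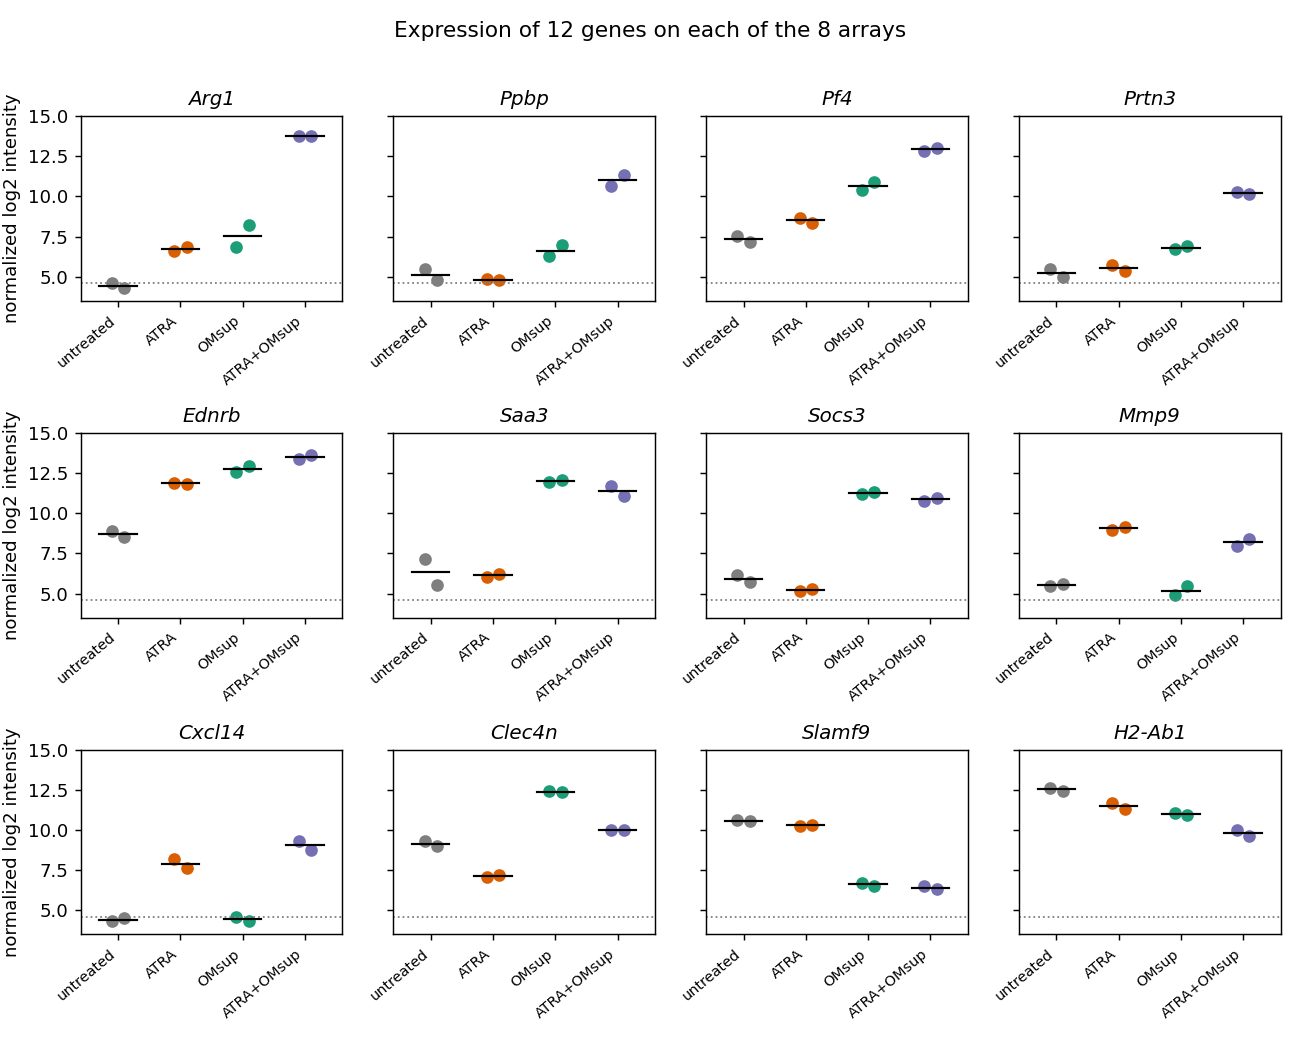
Normalized log2 intensity of 12 genes, with a point for each of the 8 arrays, a black line at the mean of the 2 arrays of a group, and a dotted line at the mean lowest level of a detected probe, 4.61. Arg1 stood at 13.75 with ATRA+OMsup against 6.72 with ATRA and 7.54 with OMsup, while Slamf9 fell from 10.59 in untreated cells to 6.62 with OMsup and 6.41 with ATRA+OMsup.

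Against untreated cells, retinoic acid alone raised a gelatinase, a chemokine, an endothelin receptor and genes of lipoproteins and of the cell cycle. It lowered the C-type lectin receptor genes Clec4n, Clec4a1 and Clec4b1. The MHC class II list was called lower as well, but not with an estimated correlation (adjusted p = 0.0639). In fry it was lower (adjusted p = 0.00484). Mmp9, which encodes matrix metalloproteinase 9, rose by 3.52 (SE 0.226, adjusted p = 2.8e-05). Ednrb, the endothelin receptor type B gene, rose by 3.14 (SE 0.163, adjusted p = 8.64e-06). The chemokine gene Cxcl14 was not above background in untreated cells and was at least 9.83-fold higher with ATRA (adjusted p = 4.14e-05). Clec4n, which encodes the receptor dectin-2 for fungal mannans, fell by 2.03 (SE 0.139, adjusted p = 3.2e-05). In all, 520 of 12793 genes or unnamed probes changed in limma's test at an adjusted p under 0.05, 300 higher and 220 lower.

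The other genes with the largest rises were Slco2b1, an organic anion transporter (3.18), Tpbgl (2.85), Pilrb1, a paired immunoglobulin-like receptor (2.83), Bcl2a1d, an anti-apoptotic BCL2 relative (2.77), and Chst15, a sulfotransferase of chondroitin sulfate synthesis (2.75). Bcl2a1d has near-identical copies, so its signal may include theirs. Among the falls, H2-M2, a non-classical MHC class I gene, was not above background with ATRA and was at least 3.45-fold lower (adjusted p = 4.14e-05). Further falls were in Lilra6 (-1.87), Galnt9 (-1.83), the lectin receptor genes Clec4a1 (-1.75) and Clec4b1 (-1.74), and Ms4a6d (-1.69). Probes of Lilra6 and of the Clec4, Ms4a and H2 genes can also bind transcripts of closely related family members.

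Of the key genes fixed in advance, Apoc2, an activator of lipoprotein lipase, rose by 2.05 (SE 0.163, adjusted p = 6.65e-05). Arg1, the arginine-degrading enzyme arginase 1, was not above background in untreated cells and was at least 4.34-fold higher with ATRA (adjusted p = 0.00304). That call ended without background correction (log2 change 0.91, adjusted p = 0.0616) and on the deposited normalized values (0.96, adjusted p = 0.0512). Tgm2, the transglutaminase 2 gene, rose by 0.91 (SE 0.18, adjusted p = 0.0164), but did not pass without the first untreated array (0.63, adjusted p = 0.132) or without either ATRA array (0.82 and 0.99, adjusted p = 0.155 and 0.0727). Ltbp1, which binds latent TGF-beta, differed by 0.13 (SE 0.201, adjusted p = 0.883). Rarb, the retinoic acid receptor beta gene, and Aldh1a2, which makes retinoic acid, were not above background in untreated cells. Their tested probes were above it on 1 of 2 ATRA arrays, and a second Rarb probe on the other; neither gene passed (adjusted p = 0.669 and 0.793). Gata6, Cyp26b1 and Alox15 were not above background on any array and Tgfb2 only on 1, so these were not tested in any comparison.

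Cell cycle genes rose together with ATRA: 9 of the 19 measured members rose and 10 did not pass (18 rose when adjusted over the list alone), with a median of 0.71 (camera adjusted p = 1.19e-15). Top2a, the DNA topoisomerase of dividing cells, rose by 1.30 (SE 0.177). Both groups were in the medium without serum when ATRA was added to OMsup. There no cell cycle gene passed over all genes and the list was not called. The list of LXR targets and lipoprotein genes, controlled by the sterol-sensing liver X receptors, had 4 of 15 members higher and 11 that did not pass (6 higher and 1 lower adjusted over the list alone), with a median of 0.27 (camera adjusted p = 1.97e-06). Apoc1 rose by 2.63, Scd1, the stearoyl-CoA desaturase gene, by 2.18 and Apoe by 0.86. Of the genes of complement and apoptotic cell uptake, 5 of 14 rose and 9 did not pass (8 higher and 1 lower adjusted over the list alone), with a median of 0.41 (camera adjusted p = 1.97e-06). They included Axl, a receptor tyrosine kinase that recognises dying cells through Gas6, which rose by 1.89, and Cfp, properdin, which rose by 0.89. These 3 calls held with an estimated correlation (adjusted p = 0.0375 for each). With members not above background in one group set to their bound, the medians of the last 2 lists were 0.13 and 0.30.

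MHC class II genes, which present extracellular antigen to CD4 T cells, fell: 7 of 9 were lower and 2 did not pass (7 adjusted over the list alone), with a median of -0.91 (camera adjusted p = 2.06e-12, but adjusted p = 0.0639 with an estimated correlation). H2-DMa fell by 1.24 and H2-Eb1 by 1.02. In the retinoic acid list, 2 of 11 members rose and 9 did not pass (3 adjusted over the list alone), with a median of 0.22 that became 0.06 with members at their bound. Its camera adjusted p was 0.0496 (0.073 with arrays scaled to a common median, and adjusted p = 0.164 with an estimated correlation). Asb2, a ubiquitin ligase subunit known as a retinoic acid target, rose by 1.70 (SE 0.205, adjusted p = 0.000875). Alternative activation genes were called higher, with 3 of 15 members up and 12 that did not pass (3 adjusted over the list alone) and a median of 0.30 that became 0.09 with members at their bound. The camera adjusted p was 0.0283 (0.0591 without background correction, 0.0552 on the deposited normalized values, and adjusted p = 0.153 with an estimated correlation). Socs2, a cytokine signalling suppressor, rose by 1.67 (SE 0.19).

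The hypoxia and glycolysis list rose by a median of 0.28 with 3 members higher, 2 lower and 12 that did not pass (7 and 2 adjusted over the list alone; camera adjusted p = 0.000655, but adjusted p = 0.0639 with an estimated correlation). Vegfa, the vascular growth factor gene, rose by 2.01. Immediate early genes respond within minutes to stimuli. They fell by a median of 0.56, with 5 of 11 lower and 6 that did not pass (2 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.00476, but adjusted p = 0.089 with an estimated correlation). The IL-6 and STAT3 list fell by a median of 0.46, with 3 of 15 lower and 12 that did not pass (1 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.000313, but adjusted p = 0.0699 with an estimated correlation). Other lists called with ATRA were the stress response of unfolded proteins and amino acids (0.22, camera adjusted p = 0.00476), cholesterol biosynthesis (0.15, adjusted p = 0.0214), TGF-beta response (-0.32, adjusted p = 0.0496) and type I interferon response (-0.17, adjusted p = 0.02). They had 2 higher and 1 lower of 18, 2 higher of 17, 1 higher and 1 lower of 11, and 1 lower of 19 (5 and 1, 2 and 0, 1 and 1, and 0 and 1 adjusted over the list alone). With an estimated correlation these gave an adjusted p = 0.188, 0.164, 0.164 and 0.425, and with arrays scaled to a common median the last 2 also did not pass (adjusted p = 0.073 and 0.0513). Within the TGF-beta list, Ltc4s, the leukotriene C4 synthase gene, rose by 1.35 and Tgfbi, an extracellular matrix protein gene, fell by 1.10.

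Lists not called with ATRA were large peritoneal macrophage genes (camera adjusted p = 0.447), NF-kB driven inflammatory genes (0.0589), PPAR targets (0.452), NRF2 targets (0.0669), glucocorticoid response (0.861), osteoclast genes (0.125) and macrophage identity (0.721). Single members of these still changed: the inflammatory cytokine gene Tnf fell by 1.29, the coagulation factor gene F10 by 1.61, the glucocorticoid-induced Tsc22d3 by 1.10, and Dcstamp and Ctsk, which serve osteoclast fusion and bone resorption, by 1.52 and 1.43. The osteoclast list had a median of -0.27 and a mean of 0.00, since Mmp9 is a member. The number of changed genes rested on each of the arrays compared: it was 222 and 228 without the first or the second untreated array, and 219 without either ATRA array.

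Omentum supernatant raised targets of IL-6 signalling, NRF2 targets, cholesterol synthesis genes and genes of hypoxia and glycolysis, and lowered cell cycle genes. The interferon and MHC class II lists were called lower as well, but not with an estimated correlation (adjusted p = 0.0813 and 0.0827). In fry both were lower (adjusted p = 0.00189 and 0.0022). Saa3, which encodes an acute phase serum amyloid, rose by 5.69 (SE 0.398, adjusted p = 7.94e-06). Socs3, a feedback inhibitor of STAT3 signalling, rose by 5.35 (SE 0.171, adjusted p = 1.08e-07). Slamf9, a leukocyte surface receptor gene, fell by 3.97 (SE 0.146, adjusted p = 2.42e-07). Pparg, the nuclear receptor gene of fatty acid metabolism, fell by 2.79 (SE 0.151, adjusted p = 1.99e-06). The limma test called 1197 changed genes or unnamed probes, 599 higher and 598 lower (620 and 492 with arrays scaled to a common median).

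Other large rises were in Tnfsf14, the cytokine LIGHT (4.62), Lrg1, a leucine-rich plasma glycoprotein above background on 1 of 2 untreated arrays (4.58), Ednrb (4.06), Hp, the haemoglobin-binding haptoglobin (3.86), and Gcnt2, an enzyme of I-branched glycans (3.71). Nrg1, a ligand of ERBB receptors, was not above background in untreated cells and was at least 16.5-fold higher with OMsup (adjusted p = 1.99e-06). Large falls were in Ccnd1, cyclin D1 (-3.13), the interferon-induced Ifit3 (-3.06), Hpgd, which inactivates prostaglandins (-2.72), Kif23, a kinesin of cell division (-2.71), the cell cycle inhibitor gene Cdkn1c (-2.71) and Cx3cr1, the fractalkine receptor (-2.65).

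Arg1 was at least 7.65-fold higher with OMsup, since untreated cells were not above background (adjusted p = 0.000178), and its 2 OMsup arrays differed, at 6.87 and 8.21. Apoc2 rose by 1.94 (SE 0.163, adjusted p = 2.95e-05). Tgm2 rose by 0.81 (SE 0.18, adjusted p = 0.0161), but did not pass without the first untreated array (0.53, adjusted p = 0.132) or the first OMsup array (0.73, adjusted p = 0.0915). Ltbp1 differed by 0.00 (SE 0.201, adjusted p = 0.999). Rarb and Aldh1a2 were not above background in either group and did not pass (adjusted p = 0.958 and 0.679).

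Genes of cholesterol biosynthesis rose: 12 of 17 were higher and 5 did not pass (14 adjusted over the list alone), with a median of 1.01 (camera adjusted p = 6.72e-16). Mvd, Fdps and Hsd17b7, enzymes of that pathway, rose by 2.01, 1.89 and 1.76, and Stard4, which carries cholesterol within cells, by 1.91. Of the hypoxia and glycolysis genes, 13 of 17 rose and 4 did not pass (14 higher and 1 lower adjusted over the list alone), with a median of 0.86 (camera adjusted p = 1.13e-14). Pfkl and Aldoc, glycolytic enzymes, rose by 2.42 and 2.35, the glucose transporter gene Slc2a1 by 2.32, and Egln3, an oxygen-sensing prolyl hydroxylase, was at least 10.5-fold higher (adjusted p = 7.92e-07). The second probes of Pfkl and Egln3 changed by only 0.615 and 0.156. Of the cell cycle genes, 13 of 19 fell and 6 did not pass (17 adjusted over the list alone), with a median of -0.85 (camera adjusted p = 1.27e-12). Tk1, Birc5 and Mcm5 had log2 changes of -1.72, -1.49 and -1.43, though the second probe of Tk1 changed by only -0.258. Of the NRF2 targets, which serve the response to oxidants, 7 of 11 rose and 4 did not pass (7 adjusted over the list alone), with a median of 0.72 (camera adjusted p = 1.58e-07), including the glutathione transferase gene Gsta3 at 2.70 (0.309 with its second probe). Of the IL-6 and STAT3 response genes, 8 of 15 rose and 7 did not pass (9 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 7.11e-06). With an estimated correlation these 5 calls held, at an adjusted p = 0.0181, 0.0181, 0.0354, 0.0491 and 0.0491.

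Of the large peritoneal macrophage genes, 8 of 16 rose and 8 did not pass (11 higher and 1 lower adjusted over the list alone), with a median of 0.66 (camera adjusted p = 8.83e-10, but adjusted p = 0.0562 with an estimated correlation). They included Saa3, Ednrb, the protease inhibitor gene Slpi at 3.34 (SE 0.215), and Thbs1, the matrix protein thrombospondin 1, at least 3.28-fold higher (adjusted p = 0.00033). Type I interferon response genes fell, 13 of 19 lower and 6 that did not pass (13 adjusted over the list alone), with a median of -1.03 (camera adjusted p = 9.96e-14, but adjusted p = 0.0813 with an estimated correlation). Ifit2 fell by 2.31, Rsad2 by 2.21 and Cxcl10 by 2.09. In the MHC class II list, 7 of 9 fell, 1 rose and 1 did not pass (1 higher and 8 lower adjusted over the list alone), with a median of -1.05 (camera adjusted p = 1e-07, but adjusted p = 0.0827 with an estimated correlation). H2-Eb1 fell by 1.86, Cd74, the class II invariant chain, by 1.59 and H2-Ab1 by 1.55.

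In the NF-kB list, 9 of 20 fell, 3 rose and 8 did not pass (4 higher and 9 lower adjusted over the list alone), with a median of -0.41 (camera adjusted p = 0.00506, but adjusted p = 0.372 with an estimated correlation). Tnf fell by 2.15 and the chemokine gene Ccl5 by 2.04, while Saa3 and Socs3, also members, rose. Immediate early genes fell by a median of 0.46, with 4 of 11 lower, 1 higher and 6 that did not pass (1 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.00938, but adjusted p = 0.0918 with an estimated correlation). Egr1 fell by 1.60 and Ier3 rose by 2.67. Complement and uptake genes rose by a median of 0.19, with 3 of 14 higher, 1 lower and 10 that did not pass (4 and 1 adjusted over the list alone; camera adjusted p = 0.0359, but adjusted p = 0.137 with an estimated correlation). Axl, a member, fell by 1.31.

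Lists not called with OMsup were those of retinoic acid (camera adjusted p = 0.931), alternative activation (0.931), LXR targets (0.28), PPAR targets (0.28), TGF-beta response (0.698), stress response (0.698), glucocorticoid response (0.703), osteoclast genes (0.28) and macrophage identity (0.612). In the alternative activation list 3 of 15 members rose, 4 fell and 8 did not pass, and its median of 0.07 and mean of 0.02 had the opposite sign to the test. Its falls included Irf4 (-1.57, above background on 1 OMsup array) and Egr2 (-1.70), transcription factor genes of that response. Nr1h3, which encodes LXR alpha, fell by 1.94. The number of changed genes was 726 and 613 without the first or the second untreated array and 711 without the second OMsup array.

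The combination gave the most changes, led by Arg1, which was not above background in untreated cells and was at least 568-fold higher with ATRA+OMsup (adjusted p = 5.88e-08), at 13.75 and 13.76 on its 2 arrays. Ppbp and Pf4, neighbouring genes of CXC chemokines stored in platelets, rose by 5.87 (SE 0.297, adjusted p = 6.37e-07) and 5.58 (SE 0.186, adjusted p = 5.68e-08). Prtn3, a serine protease of neutrophil granules, rose by 4.96 (SE 0.206, adjusted p = 1.87e-07). Markers of granulocytes went both ways in the same arrays, with Mpo higher by 0.65, Ctsg by 0.76, and Ltf lower by 1.31 (log2 change -1.31). Slamf9 fell by 4.17 (SE 0.146, adjusted p = 5.68e-08). Against untreated cells 1937 genes or unnamed probes changed in limma's test, 1008 higher and 929 lower.

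Tnfsf14 rose by 5.24, Saa3 by 5.08, Socs3 by 4.93 and Ednrb by 4.78. Falls included Hpgd (-3.99, above background on 1 ATRA+OMsup array), Pparg (-3.37), Ifit3 (-3.29), Cdkn1c (-3.27), Stap1, an adaptor of growth factor signalling (-3.22), Tnf (-2.96) and H2-Eb1 (-2.89). Apoc2 rose by 3.77 (SE 0.163, adjusted p = 2.41e-07) and Tgm2 by 2.76 (SE 0.18, adjusted p = 2.85e-06). The tested probe of Rarb was above background on both arrays only in this group, where it was at least 1.27-fold above untreated cells but did not pass (adjusted p = 0.0532). Ltbp1 differed by 0.02 (SE 0.201, adjusted p = 0.958), and Aldh1a2, above background on 1 of the 2 ATRA+OMsup arrays, did not pass (adjusted p = 0.907).

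Of the large peritoneal macrophage genes, 11 of 16 rose, 1 fell and 4 did not pass (11 and 1 adjusted over the list alone), with a median of 1.45 that became 1.07 with 6 members at their bound (camera adjusted p = 2.23e-10, but adjusted p = 0.0637 with an estimated correlation). Slpi rose by 2.89 (SE 0.215). MHC class II genes fell, 8 of 9 lower and 1 that did not pass (1 higher and 8 lower adjusted over the list alone), with a median of -1.77 (camera adjusted p = 2.23e-10, but adjusted p = 0.0637 with an estimated correlation). H2-Ab1 fell by 2.74, Cd74 fell by 2.66, and H2-Aa fell by 2.38. In the interferon list, 13 of 19 fell, 1 rose and 5 did not pass (1 higher and 15 lower adjusted over the list alone), with a median of -1.11 (camera adjusted p = 9.29e-09, but adjusted p = 0.109 with an estimated correlation).

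Hypoxia and glycolysis genes rose, 14 of 17 higher, 1 lower and 2 that did not pass (14 and 1 adjusted over the list alone), with a median of 1.26 (camera adjusted p = 1.04e-12), and this held with an estimated correlation (adjusted p = 0.0251). Pfkl rose by 2.93, Vegfa by 2.80 and Aldoc by 2.64, and Egln3 was at least 17.1-fold higher (adjusted p = 1.36e-07). The second probes of Pfkl and Egln3 changed by only 0.721 and 0.275. Cholesterol synthesis genes rose, 10 of 17 higher and 7 that did not pass (12 adjusted over the list alone), with a median of 0.95 (camera adjusted p = 2.23e-10), and this held too (adjusted p = 0.0453 with an estimated correlation). Stard4 rose by 1.68 and Mvd by 1.63. Cell cycle genes fell, 10 of 19 lower and 9 that did not pass (13 adjusted over the list alone), with a median of -0.67 (camera adjusted p = 3.27e-08, but adjusted p = 0.0637 with an estimated correlation). Birc5, a gene of mitosis, fell by 1.86.

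Immediate early genes fell by a median of 1.00, with 5 of 11 lower, 1 higher and 5 that did not pass (1 and 6 adjusted over the list alone; camera adjusted p = 0.000826, but adjusted p = 0.0637 with an estimated correlation). Egr2 fell by 2.21. The other lists called higher were NRF2 targets (median 0.41, camera adjusted p = 0.00246), complement and uptake genes (0.41, adjusted p = 0.00266), the IL-6 and STAT3 response (0.66, adjusted p = 0.00964), LXR targets (0.38, adjusted p = 0.0159) and the retinoic acid list (0.12, adjusted p = 0.0296). They had 4 higher and 1 lower of 11, 5 and 0 of 14, 7 and 2 of 15, 7 and 3 of 15, and 2 and 0 of 11 (5 and 1, 7 and 2, 8 and 4, 7 and 4, and 4 and 0 adjusted over the list alone). These 5 lists gave an adjusted p = 0.109, 0.0749, 0.109, 0.109 and 0.113 with an estimated correlation. Gsta3 rose by 3.22 (0.496 with its second probe), Apoc1 by 3.07 and Socs2 by 3.44, while Nr1h3 fell by 2.60. The alternative activation list was called higher (camera adjusted p = 0.0484, but 0.0501 with arrays scaled to a common median, and adjusted p = 0.128 with an estimated correlation). In it 6 of 15 members rose, 3 fell and 6 did not pass (6 and 3 adjusted over the list alone). Its median was -0.02 and its mean 1.00, with Arg1 as the largest member and Socs2 and Tgm2 next.

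The lists of NF-kB driven genes, PPAR targets, TGF-beta response, stress response, glucocorticoid response, osteoclast genes and macrophage identity were not called (camera adjusted p = 0.86, 0.456, 0.456, 0.545, 0.456, 0.456 and 0.678). The NF-kB list had 7 of 20 members higher and 8 lower, a median of -0.39 and a mean of 0.25, and macrophage identity a median of -0.01 and a mean of 0.09. Itgam, which encodes the integrin chain CD11b, rose by 1.49 (SE 0.225). The number of changed genes was 1114 without the second untreated array.

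**Figure D2:**
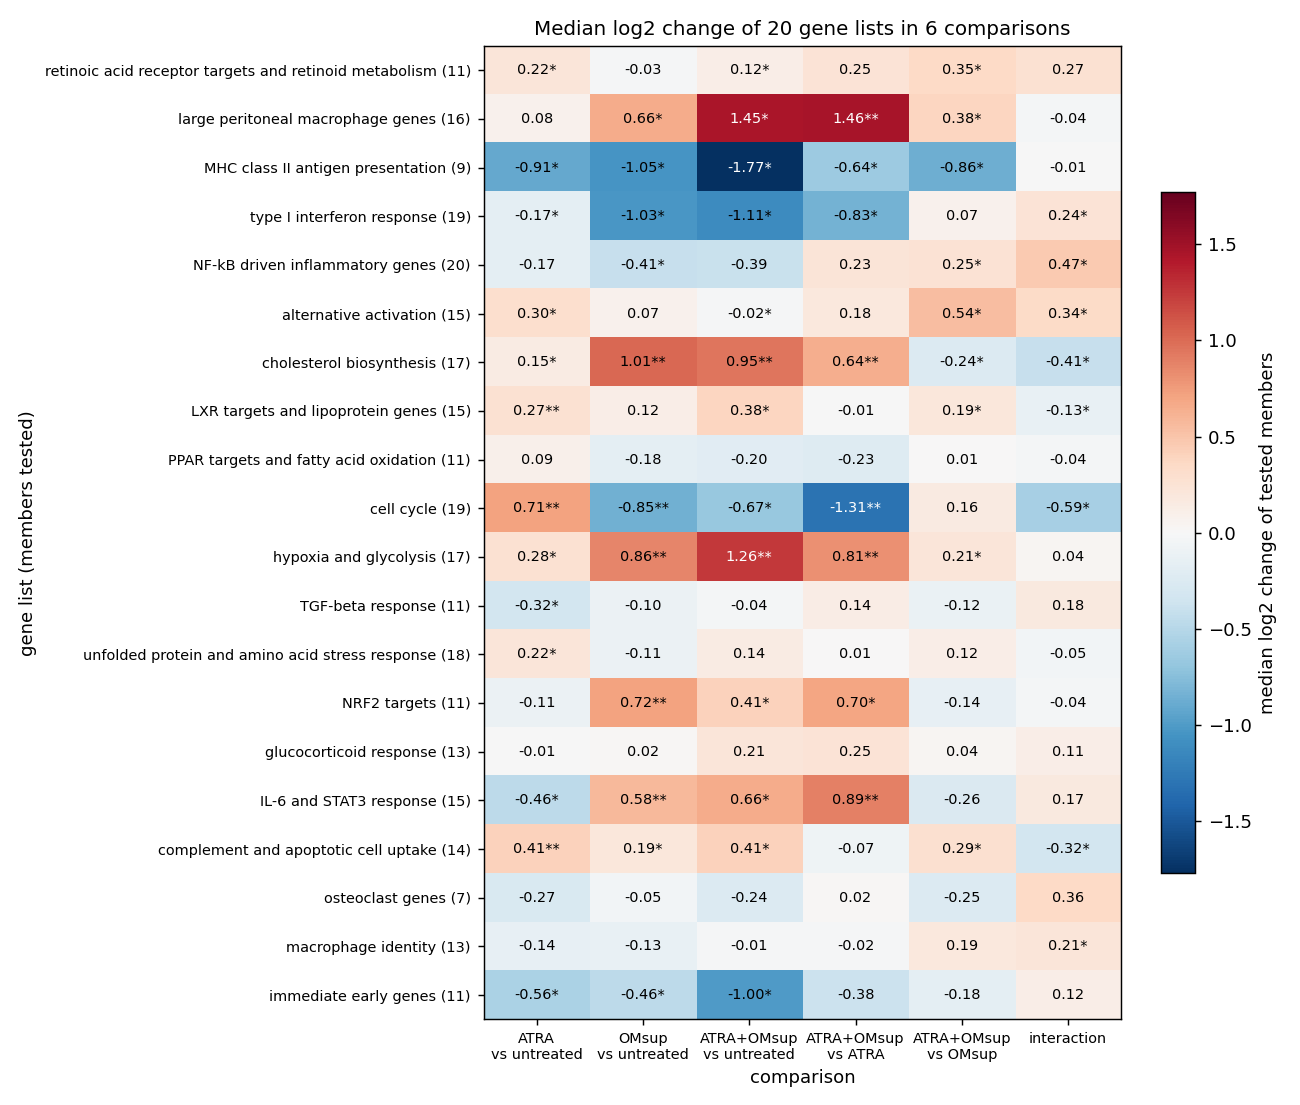
Median log2 change of the measured members of 20 gene lists, as colour and number, in each of 6 comparisons; the number of members tested is in parentheses. One star marks a camera adjusted p under 0.05 and a pair of stars a call that held with an estimated correlation, as for cell cycle genes at 0.71 with ATRA and -0.85 with OMsup.

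Adding OMsup to ATRA raised genes of hypoxia and glycolysis, of cholesterol synthesis, of the IL-6 response and of large peritoneal macrophages, and lowered 18 of 19 cell cycle genes. Arg1 rose by 7.03 (SE 0.333, adjusted p = 6.42e-07), Ppbp by 6.20 (SE 0.297, adjusted p = 6.42e-07), Socs3 by 5.65 (SE 0.171, adjusted p = 6.04e-08), Saa3 by 5.27 and Hp by 4.84. Slamf9 fell by 3.86 (SE 0.146, adjusted p = 2.11e-07), Ccnd1 by 3.08, the cell division genes Kif23 (-3.05, with another probe of opposite sign) and Prc1 (-3.00), and Ifit3 by 2.93. Tgm2 rose by 1.85 (SE 0.18, adjusted p = 8.19e-05) and Apoc2 by 1.71 (SE 0.163, adjusted p = 7.31e-05). Rarb differed by 0.30 (adjusted p = 0.333), Ltbp1 by -0.11 (adjusted p = 0.845) and Aldh1a2 by -0.20 (adjusted p = 0.567), where the tested probe of Rarb was above background on 1 ATRA array and Aldh1a2 on 1 array of each group. In all, limma called 1331 genes or unnamed probes, 637 higher and 694 lower, a balance that turned with arrays scaled to a common median (722 and 554) or cyclic loess (669 and 653).

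Of the cell cycle genes, 18 of 19 fell and 1 did not pass (19 adjusted over the list alone), with a median of -1.31 (camera adjusted p = 3.26e-22). Birc5 fell by 2.63, Tk1 by 2.55 (log2 change -1.084 with its second probe) and Mcm5 by 2.15. Hypoxia and glycolysis genes rose, 14 of 17 higher and 3 that did not pass (15 adjusted over the list alone), with a median of 0.81 (camera adjusted p = 2.92e-16). Egln3 rose by 3.86 (0.338 with its second probe). Of the large peritoneal macrophage genes, 10 of 16 rose and 6 did not pass (12 adjusted over the list alone), with a median of 1.46 (camera adjusted p = 4.03e-13). The coagulation factor gene F10 rose by 2.39, and Selp, the adhesion receptor P-selectin, was at least 5.00-fold higher (adjusted p = 1.08e-05). Cholesterol synthesis genes had 9 of 17 members higher and 8 that did not pass (12 adjusted over the list alone; median 0.64, camera adjusted p = 1.38e-09). The IL-6 and STAT3 response had 9 of 15 higher, 1 lower and 5 that did not pass (10 and 1 adjusted over the list alone; median 0.89, camera adjusted p = 1.15e-06). These 5 calls held with an estimated correlation, at an adjusted p = 0.0167, 0.0161, 0.0381, 0.0353 and 0.0381.

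Interferon genes were also called, with 11 of 19 lower (1 higher and 11 lower adjusted over the list alone) and a median of -0.83 (camera adjusted p = 2.21e-07). So were NRF2 targets, with 6 of 11 higher (6 adjusted over the list alone) and a median of 0.70 (adjusted p = 3.01e-06). MHC class II genes had 5 of 9 lower and 1 higher (7 and 1 adjusted over the list alone) and a median of -0.64 (adjusted p = 3.57e-06). These 3 lists gave an adjusted p = 0.192, 0.0586 and 0.143 with an estimated correlation. Asb2, which ATRA had raised, fell by 1.83 (SE 0.205, adjusted p = 0.000218), and Axl fell by 2.35 (SE 0.173, adjusted p = 1.15e-05). The remaining 12 lists were not called, and in 4 of them the median had another sign than the mean: TGF-beta response (0.14 and -0.02), stress response (0.01 and -0.17), osteoclast genes (0.02 and -0.16) and macrophage identity (-0.02 and 0.10). The number of changed genes was 790 and 674 without the first or the second ATRA array.

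Adding ATRA to OMsup raised Arg1, Cxcl14, Ppbp and Socs2, and lowered Clec4n and Clec4b1. The MHC class II list was called lower, but not with an estimated correlation (adjusted p = 0.0817), and none of the 9 list calls of this comparison held with one. Arg1 rose by 6.21 (SE 0.333, adjusted p = 6.95e-06). Cxcl14, above background on 1 of the 2 OMsup arrays, rose by 4.57 (SE 0.249, adjusted p = 6.95e-06). Ppbp rose by 4.38 (SE 0.297), Prtn3 by 3.42 (SE 0.206) and Socs2, above background on 1 OMsup array, by 3.37 (SE 0.19). Clec4n fell by 2.41 (SE 0.139, adjusted p = 6.95e-06), the inflammatory cytokine gene Il1b by 2.21 and the membrane metalloproteinase gene Mmp14 and Clec4b1 by 2.06 each (log2 change -2.06). Tarm1, an activating receptor gene of myeloid cells, was not above background with ATRA+OMsup and was at least 4.21-fold lower (adjusted p = 1.74e-05). In all, limma called 575 genes or unnamed probes, 349 higher and 226 lower.

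Tgm2 rose by 1.95 (SE 0.18, adjusted p = 0.000102) and Apoc2 by 1.82 (SE 0.163, adjusted p = 8.08e-05). Ltbp1 differed by 0.02 (adjusted p = 0.985). Rarb and Aldh1a2 were not above background with OMsup and did not pass (adjusted p = 0.103 and 0.881), with Rarb at least 1.26-fold higher after the addition of ATRA. MHC class II genes fell, 5 of 9 lower and 4 that did not pass (8 adjusted over the list alone), with a median of -0.86 (camera adjusted p = 4.58e-10). Alternative activation genes were higher, with 4 of 15 up, 1 down and 10 that did not pass (8 and 2 adjusted over the list alone) and a median of 0.54 (camera adjusted p = 0.000218). Cd163, a scavenger receptor of haemoglobin, was at least 3.92-fold higher (adjusted p = 0.000298). LXR targets (median 0.19, adjusted p = 0.000725), the retinoic acid list (0.35, adjusted p = 0.00158) and hypoxia and glycolysis genes (0.21, adjusted p = 0.00183) were also called higher. They had 4 up and 1 down of 15, 3 up of 11 and 2 up of 17 (5 and 1, 5 and 0, and 4 and 2 adjusted over the list alone). Apoc1 rose by 2.20, Vegfa by 2.15 and Mmp9 by 3.02. Each of these 5 lists gave an adjusted p = 0.0817 with an estimated correlation.

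Large peritoneal macrophage genes (median 0.38, camera adjusted p = 0.00158), NF-kB driven genes (0.25, adjusted p = 0.0124) and complement and uptake genes (0.29, adjusted p = 0.0284) were called higher and cholesterol synthesis genes lower (-0.24, adjusted p = 0.0129). They had 6 higher and 1 lower of 16, 6 and 3 of 20, 2 and 1 of 14, and 1 and 0 of 17 (8 and 1, 8 and 4, 3 and 1, and 1 and 2 adjusted over the list alone). The 4 gave an adjusted p = 0.205, 0.353, 0.191 and 0.203 with an estimated correlation. Fn1, the fibronectin gene, rose by 1.32, the neutrophil chemokine gene Cxcl1 by 2.09 and the monocyte chemokine gene Ccl7 by 1.62. The interferon-inducible Gbp2 rose by 1.02 in a list that was not called (camera adjusted p = 0.14). No cell cycle gene passed limma's test over all genes, and 2 of 19 had an unadjusted p under 0.05. The largest differences were 0.51 for Top2a (adjusted p = 0.184) and 0.39 for Mcm2 (adjusted p = 0.4), and the list was not called (camera adjusted p = 0.102). PPAR targets (median 0.01, mean -0.04) and osteoclast genes (-0.25 and 0.24) had a median and a mean of opposite sign. The number of changed genes was 321 without the first OMsup array.

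The ATRA effects without and with OMsup, which share no array, correlated across genes at r = 0.636, and the OMsup effects without and with ATRA at r = 0.794; genes are not independent replicates, so no p is given. Of the 520 genes changed by ATRA alone, 485 had the same sign when ATRA was added to OMsup, and 187 were called higher and 111 lower in both. Of the 1197 genes changed by OMsup alone, 1172 had the same sign when OMsup was added to ATRA, with 420 called higher and 381 lower in both. ATRA and OMsup, each against the same untreated arrays, both raised 44 genes and both lowered 73, where independent lists would share 14 and 10.3 and unchanged groups simulated against those controls shared 0 on average, since such groups give almost no calls. A further 81 genes went in opposite directions, against 24.3 for independent lists. The correlation of these effects was 0.127, against a mean of 0.502 in 100 simulations of unchanged groups, and their covariance was 0.0188 against 0.017, a difference of 0.00188. Without the first or the second untreated array the shared calls were 50 and 39 in place of 117, without either ATRA array 48, and without the second OMsup array 67. A split of the untreated arrays would leave 1 for each comparison and was not made, so part of the shared calls may come from the shared controls.

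**Figure D3:**
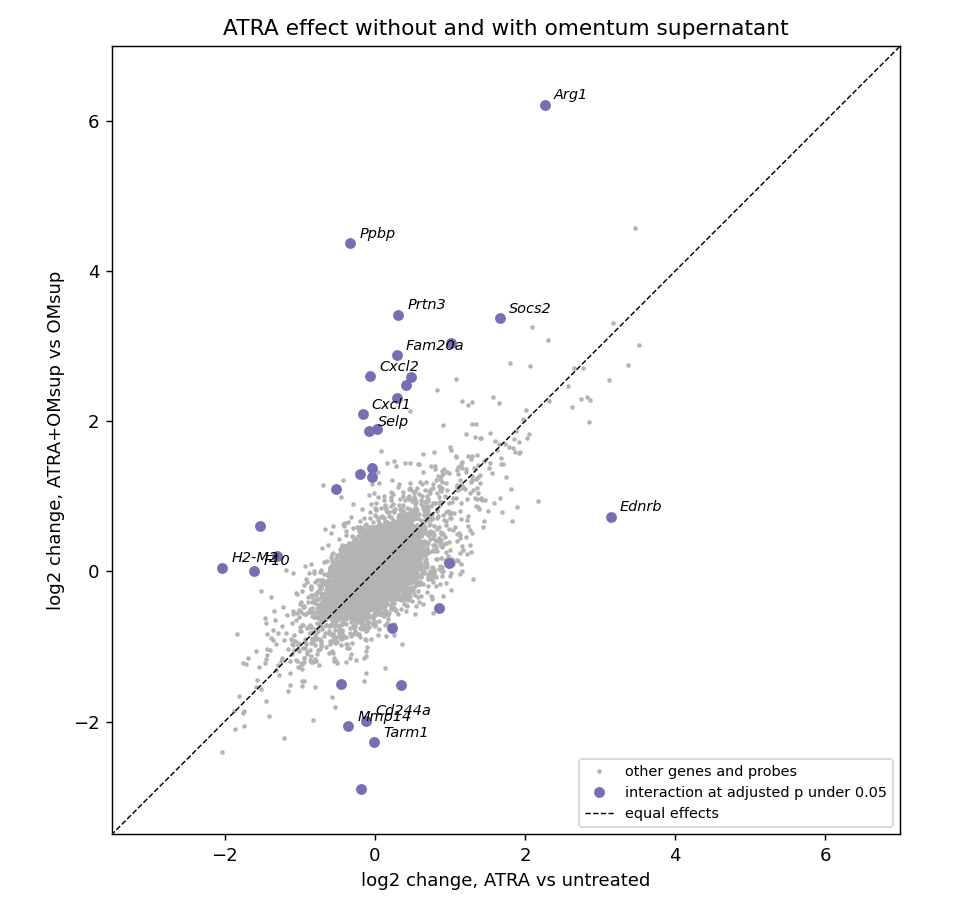
Log2 change with ATRA alone (horizontal) against the log2 change when ATRA was added to OMsup (vertical), with a point per gene or unnamed probe and purple points for the 31 with an interaction at an adjusted p under 0.05. Ppbp lies at -0.33 and 4.38, above the dashed line of equal effects, and Ednrb lies below it at 3.14 and 0.73; Arg1 was not above background in untreated cells, so its horizontal place rests on the level given to background.

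The interaction asked whether the ATRA effect differed with OMsup present; a value above 0 means that the combination exceeded the sum of the single effects on the log2 scale. Ppbp had a value of 4.70 (SE 0.42, adjusted p = 0.00164): it differed by -0.33 with ATRA alone and rose by 4.38 when ATRA was added to OMsup. Arg1 had 3.95 (SE 0.471, adjusted p = 0.00512; 5.47 with its second probe), Prtn3 3.10 (SE 0.292, adjusted p = 0.00164), the chemokine gene Cxcl2 2.66 (SE 0.251, adjusted p = 0.00164) and Fam20a, a secreted pseudokinase gene, 2.59 (SE 0.262, adjusted p = 0.00175). Ednrb had a value below 0, -2.41 (SE 0.231, adjusted p = 0.00164). Its levels were 8.72 untreated, 11.86 with ATRA, 12.78 with OMsup and 13.50 with both. The call ended with the mean of its probes (-1.56), and its other probes gave only -1.112 and -1.144. In limma's test 31 genes or unnamed probes passed, 21 above and 10 below 0, of which 24 had a gene symbol.

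Of the other values above 0, Cxcl1 had 2.25 (SE 0.291, adjusted p = 0.00783), H2-M2 2.08 (SE 0.208, adjusted p = 0.00173), Selp 1.95 (SE 0.263, adjusted p = 0.0099), Socs2 1.70 (SE 0.268, adjusted p = 0.0315) and F10 1.61 (SE 0.222, adjusted p = 0.0112). A value above 0 need not mean a rise above each agent alone. F10 stood at 8.18 untreated, 6.57 with ATRA, 8.96 with OMsup and 8.96 with both. Cxcl1 and Cxcl2 stood lower with OMsup (5.07 and 4.46) than untreated (6.38 and 5.45). H2-M2 was above background only in untreated cells, so the combination had no room to lower it below the single agents. The labels do not say whether untreated cells received the medium without serum. An effect of that medium on H2-M2 therefore cannot be told apart from an effect of the agents. Untreated cells were also not above background for Arg1, Fam20a and Selp, and OMsup-treated cells for the probe of Cxcl2, so these interactions depend on the level given to background. For Cxcl2 a lower level with OMsup would make the value larger. Values below 0 were found for Tarm1 (-2.27, SE 0.222, adjusted p = 0.00168) and Cd244a, a receptor of natural killer and myeloid cells (-1.88, SE 0.207, adjusted p = 0.00306), both above background only with OMsup alone. Mmp14 (-1.71, SE 0.213, adjusted p = 0.0058) and the cohesin protector gene Sgo2a (-1.35, SE 0.209, adjusted p = 0.0283) were below 0 as well. Tgm2 (1.04, SE 0.255, adjusted p = 0.237), Ltbp1 (-0.11, adjusted p = 1) and Apoc2 (-0.23, adjusted p = 1) did not pass, nor did Rarb and Aldh1a2, which were below detection in most arrays (adjusted p = 1).

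Cell cycle genes had a median interaction of -0.59 (camera adjusted p = 1.57e-13, but adjusted p = 0.0509 with an estimated correlation). No member passed limma's test over all genes, 6 of 19 were below 0 adjusted over the list alone, and 11 had an unadjusted p under 0.05. NF-kB driven genes had a median of 0.47, with Cxcl1 and Cxcl2 called (5 above and 1 below 0 adjusted over the list alone; camera adjusted p = 1.51e-08, but adjusted p = 0.151 with an estimated correlation). Alternative activation genes had a median of 0.34, with Arg1 and Socs2 called (6 above and 2 below 0 adjusted over the list alone; camera adjusted p = 5.96e-05, but adjusted p = 0.0509 with an estimated correlation). Further lists called without any member that passed over all genes in limma's test were cholesterol synthesis (median -0.41, camera adjusted p = 4.57e-07), complement and uptake (-0.32, adjusted p = 5.51e-05), type I interferon response (0.24, adjusted p = 2.45e-05), LXR targets (-0.13, adjusted p = 0.0198) and macrophage identity (0.21, adjusted p = 0.0452). At an unadjusted p under 0.05 these had 6 of 17, 5 of 14, 4 of 19, 3 of 15 and 4 of 13 members. With an estimated correlation they gave an adjusted p = 0.0509, 0.0509, 0.216, 0.151 and 0.19, and the LXR call also ended without background correction (0.0906) and with the deposited normalized values (0.0874). Large peritoneal macrophage genes had a median of -0.04 and a mean of 0.19 and were not called (camera adjusted p = 0.0527), and the uncalled MHC class II (-0.01 and 0.06) and hypoxia (0.04 and -0.01) lists also had a median and a mean of opposite sign.

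The number of genes with an interaction was 19 and 16 without the first or the second untreated array and 20 and 14 without the first or the second ATRA array. Calls ended for Cxcl1 without the second untreated or the second ATRA array (2.21 and 2.20), and for Mmp14 without the second ATRA array (-1.73). They also ended for Selp without any of the 4 untreated and ATRA arrays (1.89 to 2.01), for F10 without any of those or the first OMsup array (1.44 to 1.66), for Socs2 without any of 7 arrays (1.54 to 1.87) and for Sgo2a without any of the 8 (-1.38 to -1.32).

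Markers of other cell types were counted in each group. None of the 7 mesothelial markers with a probe passed the detection filter, and 1 of the adipocyte markers, 4 of the fibroblast markers and 2 of the B cell markers did, with no more than 2 of a list above background on both arrays of a group. Of these, only the fibroblast marker Col6a1 changed, lower with OMsup. Of the T and NK cell markers, Il7r, which encodes the receptor of interleukin 7 and is also found in macrophages, was measured at 10.67 in untreated cells and fell by 0.89 with ATRA+OMsup (adjusted p = 0.00198). Of 9 measured granulocyte markers, S100a8 fell by 0.86 with ATRA (adjusted p = 0.0353), 3 rose and 3 fell with OMsup, and 3 rose and 2 fell with ATRA+OMsup. With OMsup the rises were in Prtn3 (1.54), Ctsg (1.19) and Mpo (0.89), and Ltf fell by 1.09. Of 6 measured megakaryocyte and platelet markers, the transcription factor gene Nfe2 rose by 0.79 with OMsup and 0.95 with ATRA+OMsup, and Vwf, von Willebrand factor, fell by 1.11 with ATRA+OMsup. Clec9a, a dendritic cell receptor, was above background on both arrays only with ATRA and was called higher there (adjusted p = 0.00655). The stem cell factor receptor gene Kit was lower in both groups with OMsup, where it was not above background (adjusted p = 0.0093 and 0.00758). Of the macrophage identity genes, 5 of 13 rose, 3 fell and 5 did not pass with ATRA+OMsup (5 and 5 adjusted over the list alone). Among those that did not pass, Lyz2, Adgre1 and Csf1r differed by -0.01, -0.08 and -0.01 (adjusted p = 0.979, 0.807 and 0.977).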

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

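The test of background for genes well above it was chosen only after the result was seen; the other tests in this part were planned or written before their values were known.

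The results looked at again here are those where the effect of ATRA differed with OMsup present. Values above 0 were found for Ppbp (4.70), Arg1 (3.95), Prtn3 (3.10), Cxcl2 (2.66), Fam20a (2.59), Cxcl1 (2.25), H2-M2 (2.08), Selp (1.95), Socs2 (1.70) and F10 (1.61). Values below 0 were found for Ednrb (-2.41), Tarm1 (-2.27), Cd244a (-1.88), Mmp14 (-1.71) and Sgo2a (-1.35). Among the lists, NF-kB driven genes (0.47), alternative activation (0.34), type I interferon response (0.24) and macrophage identity (0.21) lay above 0, and cell cycle (-0.59), cholesterol synthesis (-0.41), complement and uptake (-0.32) and LXR targets (-0.13) below; none of these 8 list calls held with an estimated correlation (adjusted p = 0.0509 to 0.216).

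Ppbp, Pf4 and Prtn3 are known best from platelets and neutrophil granules, so their rise with ATRA+OMsup could come from other cells in the cultures. The other 8 measured granulocyte markers had a median change of -0.24 in that comparison, but they went both ways. Mpo (0.65) and Ctsg (0.76) were called higher and Ltf (-1.31) and Camp (-0.63) lower, so the median cannot speak on precursors. None of the 8 rose by as much as 1, while Prtn3 rose by 4.96. More cells with these markers would therefore not account for the size of its rise. Of the other megakaryocyte and platelet markers, 1 was called higher, Nfe2 at 0.95, and Vwf fell by 1.11. Pf4 reached a level of 12.93, and which cells it came from was not tested, since single cells were not measured. Granulocyte markers were above background in these arrays, such as S100a8 at 9.78 and Mpo at 7.92, so such cells would not be beneath detection. Of the megakaryocyte and platelet markers, Itga2b, Gp1bb, Gp5 and Gp6 did not pass the detection filter. Treml1, Nfe2 and Vwf were above background on both ATRA+OMsup arrays. Whether a small number of megakaryocytes or platelets was present stays open.

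An interaction above 0 may arise when a low level in untreated cells is hidden by background. Of the 21 genes or probes with a value above 0, 10 were above background on all 8 arrays, which leaves the question open for the others, Arg1 among them. It also stays open for those of the 10 with an untreated mean close to the lowest detected level of 4.61, such as Ppbp (5.12) and Prtn3 (5.26). Cxcl1 was low with OMsup (5.07) but less so in untreated cells (6.38). A lower level hidden with OMsup would make its value larger, so it would not create a value above 0. For Akap7, F10, Flywch2, Hopx and St3gal5, whose 4 group means all lay over 1 log2 unit above background, 5 of 5 calls held under each of 3 other background settings. These genes were picked for lying above background, so their calls say nothing about the other genes. Under scaling 20 of the 21 calls held and under cyclic loess 21, so the normalization is an unlikely cause. An effect of the medium on all the treated groups, which the labels leave open, would also enter every interaction and could not be tested. Values below 0 could come from saturation. The median ATRA+OMsup level of those genes lay 6.85 log2 units under the highest array value. Some of them, such as Tarm1 (4.4) and Cd244a (4.43), were at background in that group, so the median cannot speak for the bright ones. Ednrb was 1.17 units below the highest value and an unnamed probe 1.4, so for these saturation is possible.

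Same-numbered arrays of the 3 treated groups deviated together: the replicate deviations correlated at 0.46 between ATRA and OMsup, 0.433 between ATRA and ATRA+OMsup and 0.532 between OMsup and ATRA+OMsup, and at -0.01 to 0.209 with the untreated group. The normalization could have done this, but the mean of the 3 correlations was 0.47 under the lower of scaling and cyclic loess. A shared culture or processing batch is possible: the mean was 0.48, and on the third principal component, with 11.2% of the variance, the first array lay below the second in all 4 groups (untreated -4.60 and -0.42, ATRA -7.60 and 12.95, OMsup -9.73 and 16.48, ATRA+OMsup -18.89 and 11.81). The labels give no culture, day or chip, so this stays open. Between the replicate numbers 274 genes differed, 189 higher and 85 lower in the second, and no list was called.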

How the results depend on the processing

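No alternative was chosen after the result was seen, but the size of change at which a correlation is said to have moved was set only then. A chip or slide block was not run, since the files used here give no chip.

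Named genes were run under every alternative for single genes, which leaves out probes taken singly and the 2-fold limit, and no called change reversed its sign there; other probes of 7 genes did have the opposite sign, in 10 values. A value that did not pass and changed sign was counted as unchanged. Of 364 calls of named genes, 266 held under all of these and 98 ended under at least 1, of which 54 ended only when an array was left out. Lists were run only with the estimated correlation, fry, scaling, no background correction, normexp without controls, the deposited normalized values, no filter and the block, and no list call reversed there. Of 62 list calls, the estimated correlation ended 47, fry 7, scaling 4, and no background correction and the deposited normalized values 2 each. New list calls came with fry (16), no filter (7), normexp without controls (3), no background correction (3), the deposited normalized values (3) and scaling (1).

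Requiring a change of at least 2-fold left 238 of 520 genes with ATRA, 473 of 1197 with OMsup, 726 of 1937 with ATRA+OMsup, 509 of 1331 for ATRA+OMsup against ATRA, and 272 of 575 against OMsup. Of the 117 genes changed in the same direction by ATRA and by OMsup 30 were left, since small changes were dropped. With only probes detected on all 8 arrays, 9599 genes were tested and 12 interactions were called, all among the 31. Of those 31, 15 did not enter, and for the others that did not pass the cause was not tested.

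With the replicate number as a block, 924 genes changed with ATRA, 899 for ATRA+OMsup against OMsup and 65 in the interaction. The retinoic acid list with ATRA (camera adjusted p = 0.0545) and alternative activation with ATRA+OMsup (0.0855) did not pass there, and 4 other list calls were new, such as NF-kB driven genes with ATRA (0.0474). Same-numbered samples share only a number in the labels, and their deviations correlated at -0.01 to 0.532, so this paired result is given here only.

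Leaving out 1 array at a time gave 219 to 595 genes with ATRA, 613 to 1323 with OMsup, 1114 to 1911 with ATRA+OMsup, 674 to 1287 for ATRA+OMsup against ATRA, 321 to 481 against OMsup, 14 to 34 in the interaction and 39 to 128 shared by ATRA and OMsup. The lowest counts came from leaving out an array of the groups compared, where fewer samples remain.

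The correlation of the ATRA effect without and with OMsup, 0.636, was 0.687 without background correction, 0.686 on the deposited normalized values, 0.777 over called genes only, and 0.525 to 0.643 with 1 array left out. That of the OMsup effect, 0.794, was 0.826, 0.825 and 0.875 in the same order, 0.764 without a filter, and 0.716 to 0.79 with 1 array left out. Choosing called genes raises a correlation by construction; for the other values the cause was not tested.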

Other observations

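The test of gene neighbours and the 3 tests of receptor families were chosen only after the result was seen.

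Several of the largest falls with ATRA were in families of myeloid surface receptors. Clec4 genes encode C-type lectin receptors of microbial and glycan ligands, Lilr and Pir genes encode paired immunoglobulin-like receptors that raise or restrain activation, and Ms4a genes encode membrane proteins that modulate such receptors. ATRA lowered 5 of 8 measured members of the Clec4 family, 3 of 5 of the Lilr and Pir families and 1 of 7 of the Ms4a family. OMsup acted the other way on Clec4n, which rose by 3.24 (adjusted p = 3.99e-07 in limma) and fell by 2.41 when ATRA was added.

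A shared regulation of these families by ATRA is a hypothesis that the members which did not lead to it can test. Without the leading genes, the addition of ATRA to OMsup gave a median of -0.48 for 5 other Clec4 genes (camera adjusted p = 1.25e-06 over the 3 families), -0.75 for 3 Lilr and Pir genes (adjusted p = 0.00164) and -0.51 for 6 Ms4a genes (adjusted p = 0.000253). The ATRA effect in the absence of OMsup gave -0.40, -0.57 and -0.30 for the same genes (adjusted p = 7.46e-06, 0.000317 and 0.0169). With an estimated correlation only the Clec4 calls held, at an adjusted p = 0.02 with OMsup and 0.0259 without it. Lilr and Pir genes gave 0.0594 and 0.0559 and Ms4a genes 0.0594 and 0.17, so for these families the question stays open. Among the 5 other Clec4 genes only Clec4a3 (-1.31 with and without OMsup) and Clec4e (-1.15 with and -1.23 without it) passed singly. Clec4e was also a called member of the NF-kB list with ATRA. Clec4a4, Clec4d and Clec4g passed in neither comparison, so a fall of the whole family was not shown. Probes of such related genes may bind each other's transcripts, which would make members move together. Probes specific to each gene, or reads of the whole transcripts, could separate this from a shared response.

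Ppbp, Cxcl1 and Cxcl2, CXC chemokine genes with an interaction above 0, are neighbours in the genome, with Pf4 among them. Of 17 genes with such a value that could be placed, 4 lay within 20 neighbouring tested genes, these 3 and Hopx, and 0 of 10000 random gene sets had as many (permutation p = 1e-04, the smallest this test can give). The test counts the genes that prompted it, so it decides nothing about the neighbourhood. None of the 15 tested genes between Hopx and Ppbp passed, nor did Pf4 (1.10, adjusted p = 0.223 in limma). No cause was tested.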
